A study of Mus musculus with 31 samples.

How the data were processed

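RNA abundance was measured on Affymetrix Mouse Genome 430 2.0 arrays in 31 mouse samples. They were 12 untreated thymi and 19 thymic tumors induced with ENU (N-ethyl-N-nitrosourea, an alkylating mutagen), from NDR1 wild-type (WT), heterozygous (HT) and homozygous mutant (KO) C57BL/6 mice. NDR1 is the protein kinase encoded by Stk38. The sample titles name thymocytes and tumor cells, while the source and tissue labels name thymus, and whether cells were isolated from the organ is not given in the sources used here. Samples are called thymus, or thymi, and tumors below. Per the labels, each genotype had 2 female and 2 male thymi. The tumors were from 5 female WT mice, from 6 female and 1 male HT mice, and from 6 female and 1 male KO mice.

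The deposited values were normalized intensities, 1 per probe set and array, made with GCRMA (a background correction, normalization and summary of probe intensities), per the submitters' processing notes. The version of that program was not given in the sources used here. The values were on a linear scale, and every array had the same median of 20.0 and almost the same 75th percentile. The labels' labelling protocol names an assay for whole-transcript arrays, whereas this array reads the 3' ends of transcripts. The number of arrays limits the precision of every value below. The labels do not state whether each array came from a separate animal, which limits what the p-values can stand for.

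The table held 45101 probe sets, of which 1 had no value on any array. A single gene was named for 34944 probe sets, several genes for 932 and no gene for 9224. Gene names came from the probe annotation supplied with the series, and chromosomes and gene order from a RefSeq gene table of assembly GRCm38.p6. The Entrez gene of 99.4% of the single-gene probe sets was in that table. Values were turned to log2(value + 1). Each gene was represented by its probe set of highest mean over all arrays, and genes whose mean was above the 25th percentile (3.61 on the log2 scale) were kept. This left 14017 of 18192 genes (77.0%).

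Fits were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test, Benjamini-Hochberg adjustment over all genes tested), with sex as a covariate and a threshold of adjusted p under 0.05. Thymus genotypes were compared within the 12 thymus arrays and tumor genotypes within the 19 tumor arrays. Tumors were compared with thymus in a fit of all 31 arrays, as the mean of the genotypes' differences, per genotype, and as the difference between genotypes. Male and female thymi were compared in the thymus fit. The sex coefficient in the fit of all arrays came mostly from thymi, since 2 tumors were male. Single measures were compared by 2-sided exact permutation tests of the difference of means.

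Of 30 gene lists written before the data were examined, 28 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The tests were repeated with an estimated correlation. Members of a list were counted past the threshold over all genes tested and adjusted over the list alone. The list of anti-apoptotic BCL2 family genes, with 4 members measured, and that of sex-linked genes, with 4, were not tested. Genes were named by a rule set before the data were examined. It took Stk38, Stk38l and Bcl2l11 always, up to 10 largest rises and 10 largest falls among genes past the threshold (5 for the comparisons within 1 genotype), the 3 smallest p values per direction where no gene passed, and up to 4 members of each list called. Genes named outside it are said to be chosen after their values were seen.

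RNA integrity was read as the log2 ratio of 3' to 5' control probe sets of actin and Gapdh. The fits were tested on simulated data for the real genes, with 200 genes changed by known amounts. For thymus KO against WT (14017 genes), 52.2% of changes of 0.5, 93.8% of changes of 1 and 98.6% of changes of 2 on the log2 scale were recovered. For thymus HT against WT these shares were 48.6%, 93.1% and 100%, and for thymus KO against HT 54.8%, 92.6% and 100%. For tumor KO against WT they were 4.69%, 29.2% and 54.7%, for tumor HT against WT 1.49%, 26.2% and 63.2%, and for tumor KO against HT 4.35%, 29.7% and 73.1%. For tumor vs thymus they were 17.6%, 58.0% and 87.7%. Within WT they were 1.30%, 26.2% and 64.5%, within HT 2.78%, 23.6% and 67.9%, and within KO 9.23%, 32.0% and 75.0%. For the difference of tumor vs thymus between HT and WT they were 0%, 8.33% and 22.0%, and between KO and WT 0%, 10.8% and 52.2%. For thymus male vs female they were 57.6%, 94.1% and 100%. With fewer changed genes than 200 the adjusted threshold is stricter, so these shares may overstate recovery where few genes passed. Unchanged genes called falsely numbered 8 for thymus KO against WT, 12 for HT against WT, 7 for KO against HT and 10 for male vs female. They numbered 2 to 4 between tumor genotypes and 0 or 1 in the comparisons of tumors with thymus. A shift of the mitosis list was called in all 13 comparisons, with 0 of the other lists called. The run was set to stop unless the shifted list was called, so that part was a condition of the run. Simulated errors were independent between genes, so the 0 does not show how often correlated genes give false list calls. In the real data 129 of 136 list calls were lost with an estimated correlation.

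Alternatives chosen before the data were examined were other scalings, filters, probe set summaries, a pseudocount of 16, fits without sex, of female arrays or of the 2 groups alone, a replicate block, trend and robust eBayes, array weights, a log2 fold threshold of 1, an estimated correlation and leaving out each array. Chosen after seeing the data were the 3'/5' ratio as a covariate and leaving out the 4 tumors with the highest mean of the B cell list. Probe sets without a single gene name were kept out of the gene fits. Figures were drawn with matplotlib 3.10.9.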

Results

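The data were 31 arrays of RNA from untreated thymus and from ENU-induced thymic tumors of mice labelled wild-type (WT), heterozygous (HT) or homozygous mutant (KO) for Stk38, the gene of the kinase NDR1. Sample titles name thymocytes and tumor cells, while source and tissue labels name thymus, so a cell type marker below describes the RNA on the array and not necessarily the organ. There were 4 thymus arrays per genotype, and tumor arrays numbered 5 for WT, 7 for HT and 7 for KO. Values below are log2(intensity + 1), every array had a median intensity of 20.0, and fold changes are differences of these log2 values. The median SD over genes within a group was 0.173 in WT thymus, 0.174 in HT thymus and 0.187 in KO thymus. In tumors it was 0.447 for WT, 0.603 for HT and 0.655 for KO.

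Stk38 is the targeted gene, so its signal was read first in every group. Its main probe set had a mean of 11.86 ± 0.148 (SD, n = 4) in WT thymus, 11.44 ± 0.115 in HT thymus and 10.92 ± 0.329 in KO thymus, an order that follows the labels. KO differed from WT by -0.94 (2-sided exact permutation p = 0.0286, the smallest possible with 4 against 4 arrays; 0.0857 after adjustment over 6 comparisons). HT differed from WT by -0.42 with the same exact p of 0.0286, while its limma adjusted p was 0.467. In intensity, the KO thymi had a mean of 1973 ± 465 (SD, n = 4) and the WT thymi 3729 ± 382. Another Stk38 probe set was 0.27 higher in KO than in WT thymus (exact permutation p = 0.257, n = 4 each), so the fall of Stk38 is uncertain between probe sets. Which part of the gene is disrupted is not given in the sources used here, and a probe set outside that part checks no label.

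In tumors the Stk38 signal did not separate the genotypes. Means were 12.15 ± 0.724 (SD, n = 5) for tumors labelled WT, 11.77 ± 0.755 (n = 7) for HT and 11.09 ± 1.89 (n = 7) for KO. The exact permutation p was 0.259 for KO against WT, 0.418 for HT against WT and 0.381 for KO against HT. Tumors labelled KO ranged from 8.73 to 13.08, and 4 of the 7 were at or above the lowest WT tumor. Stk38l, which encodes the related kinase NDR2, and Bcl2l11, which encodes the pro-apoptotic protein BIM, passed no genotype comparison in thymus or tumors.

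**Figure D1:**
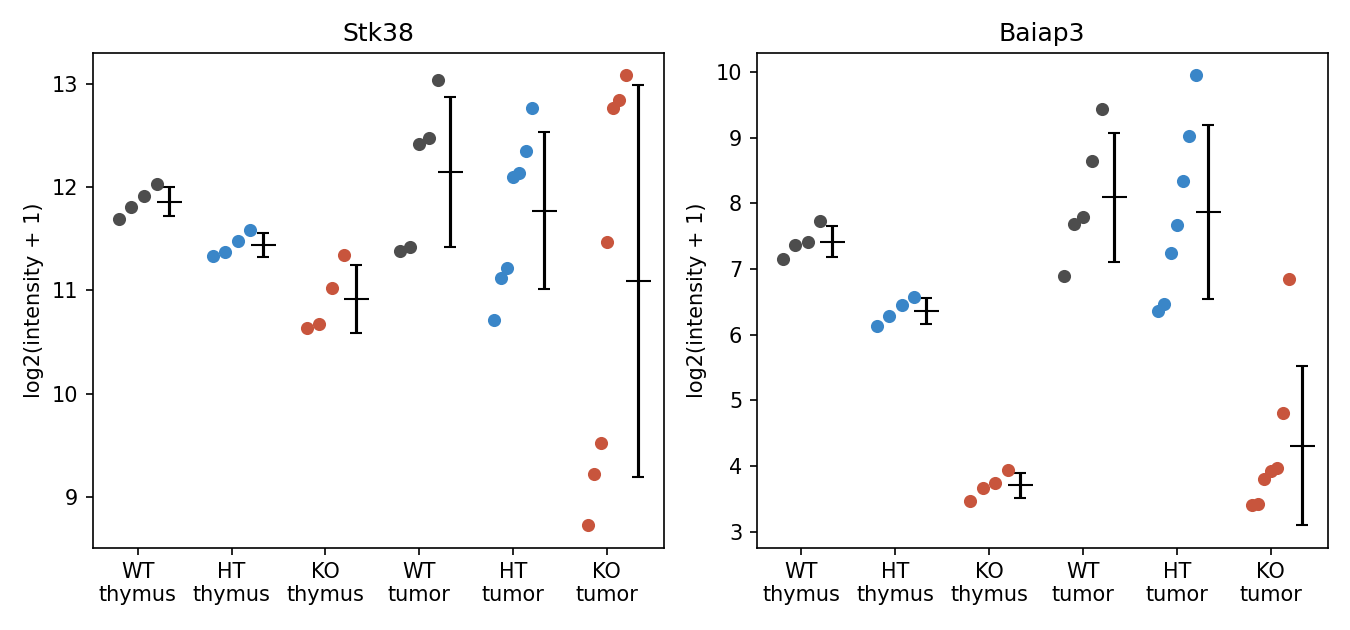
Log2(intensity + 1) of Stk38 and Baiap3 on each array, by genotype and tissue, with the group mean and SD as a bar beside the points. Stk38 means fell from 11.86 in WT to 10.92 in KO thymus, while tumors labelled KO ranged from 8.73 to 13.08; Baiap3 was 3.70 in KO thymus and 7.42 in WT thymus.

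The comparison of KO with WT thymus asks which genes differ with the NDR1 genotype before any tumor arises. Baiap3, which encodes a protein of vesicle transport, had the largest fall, and the zinc-finger genes Zfp994, Zfp40, Zfp52 and Zfp943 and the DNA repair gene Eme2 also fell, whereas the zinc-finger gene Zfp760 rose. S1pr1 and Itgb7, both used by maturing T cells to move out of the thymus and into tissues, rose. Most of the genes that changed lay on chromosome 17, where Stk38 itself lies. In limma, 26 of 14017 genes passed adjusted p under 0.05, of which 12 were higher and 14 lower in KO. Baiap3 fell by 3.72 on the log2 scale (SE 0.132, adjusted p = 1.01e-07), from 7.42 ± 0.239 to 3.70 ± 0.192 (SD, n = 4 each). Zfp994 fell by 2.36, Eme2 by 2.09, Anks1 by 1.83, Zfp40 by 1.62, Gnptg by 1.38, Zfp52 by 1.08 and Zfp943 by 0.81 on the log2 scale. Slc49a4 rose by 1.59 (adjusted p = 0.000153), Zfp760 by 1.29, Sh3gl3 by 1.27, Nron by 1.12, Hspbap1 by 1.03, S1pr1 by 0.91 (adjusted p = 0.0411), Hs3st3b1 by 0.70, Itgb7 by 0.67 (adjusted p = 0.0388) and Gimap3 by 0.64. Zfp945 (+2.71) and Gfer (-0.80) passed but are uncertain, since another probe set of each went the opposite way (-3.83 and +0.97). A further Zfp945 probe set went the same way (+0.76). Other Eme2 probe sets, of low signal, changed by -0.02 and -0.13, and the other Zfp943 probe set by -0.17, none at unadjusted p under 0.05 in limma. The falls of Eme2 and Zfp943 thus rest on a single probe set each. Baiap3, Zfp994, Anks1, Gnptg and Zfp760 had no other probe set above the filter, so their changes also rest on 1 each. S1pr1, Itgb7, Gimap3, Hs3st3b1 and Sh3gl3 lost the threshold in 11 to 13 of 21 alternative settings each, and Baiap3 in 0 of 21. The count was 17 without WT thymus F_01, 13 without WT thymus F_02, 16 without WT thymus M_02, 16 without KO thymus F_01 and 17 without KO thymus M_02.

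On chromosome 17 lay 16 of the 26 genes, including Stk38, against 4.96% of all genes tested. With Stk38 left out, 15 of 25 did (Fisher's exact p = 4.78e-14, odds ratio 29.4). All 15 lay on the same side of Stk38 in gene order, within 217 protein-coding genes of it, out of 1059 on the chromosome. Anks1 was the nearest, 24 genes away, and the other 14 lay 101 to 217 genes away, while 0 of the 18 genes tested between Anks1 and Stk38 and 0 of the 434 tested on the other side of Stk38 passed. In HT thymus all 15 had values between those of WT and KO. So did the genes that passed on other chromosomes, except Hs3st3b1 and Nron. Slc49a4 and Hspbap1, 2 further genes, lay on chromosome 16.

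**Figure D2:**
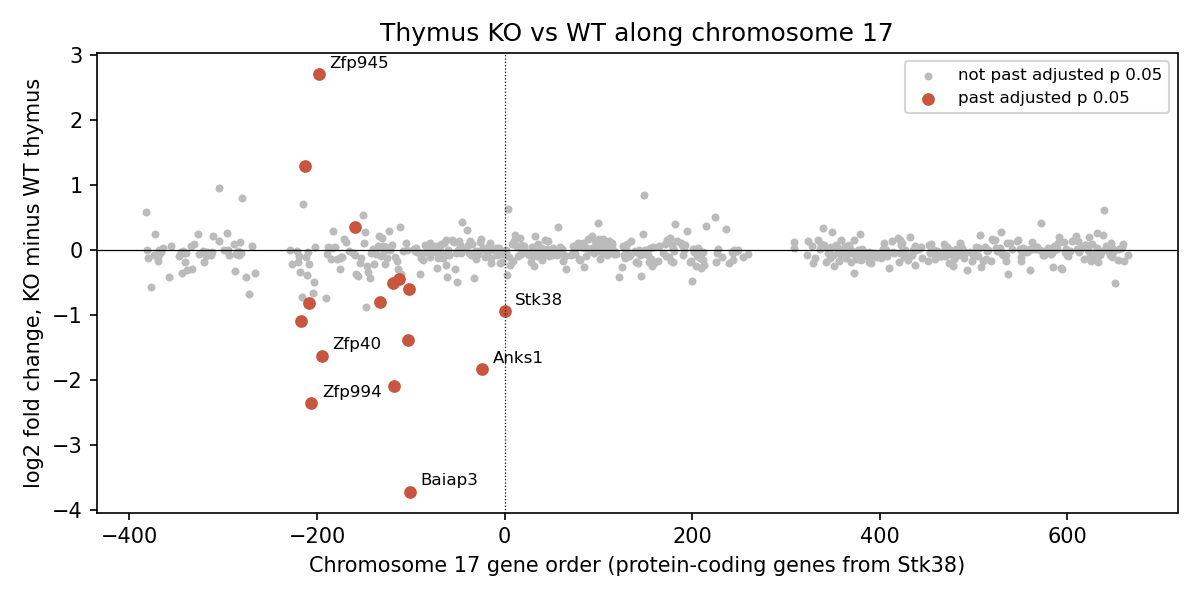
Log2 fold change of KO minus WT thymus (4 arrays each) for tested chromosome 17 genes, by gene order in protein-coding genes from Stk38 at 0; red points passed adjusted p under 0.05 in limma. The 15 genes other than Stk38 that passed all sit at negative order, from -217 to -24.

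Of the gene lists, that of single-positive and mature T cell genes was higher in KO than WT thymus (camera adjusted p = 8.1e-08, and adjusted p = 0.0375 with an estimated correlation). Of its 16 measured members 2 rose, and 5 did when adjusted over the list alone, with a mean of +0.25 over the list. Klf2, which drives S1pr1, was +0.65 and Gimap4 +0.34, neither passing. Interferon response genes had a mean of +0.36, with Xaf1 at +0.46 and 0 of 16 members passing (adjusted p = 2.34e-10, but adjusted p = 0.259 with an estimated correlation). Neutrophil markers had a mean of -1.51, with Ngp at -3.21 and S100a8 at -1.94 and 0 of 10 members passing over all genes, while 7 fell when adjusted over the list alone (adjusted p = 4.15e-12, but adjusted p = 0.187 with an estimated correlation).

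HT thymus was compared with WT thymus to see whether losing 1 copy has an effect. Zfp945 and Baiap3, both on chromosome 17, and the noncoding RNA gene Nron were the genes that passed. In limma these were 3 of 14017 genes, with Zfp945 at +2.09 (adjusted p = 0.000489, uncertain between probe sets), Nron at +1.28 (adjusted p = 0.0168) and Baiap3 at -1.06 (adjusted p = 0.0242). All 3 also passed in KO against WT in the same direction. Both comparisons use the same WT arrays. With separate pairs of WT arrays 1 gene was shared in either arrangement. Simulated unchanged groups shared 0 on average, but such groups are bound to pass few genes, so this says little about the shared arrays. The count of 3 became 1 without WT thymus F_02, WT thymus M_01, HT thymus F_01, HT thymus F_02 or HT thymus M_02. KO against HT thymus gave 8 genes, 2 higher and 6 lower. Baiap3 fell by 2.66 on the log2 scale (adjusted p = 4.19e-06), Zfp994 by 1.75, Eme2 by 1.55, Anks1 by 1.12 and Zfp40 by 1.06, while Slc49a4 rose by 0.97 and Hs3st3b1 by 0.83. Of 21 alternative settings, Hs3st3b1 lost the threshold in 13, Slc49a4 in 12, Anks1 in 11, Zfp994 in 8, Zfp40 in 7 and Eme2 in 3. For KO against HT the count was 2 without HT thymus F_01, HT thymus M_02 or KO thymus F_01, 3 without HT thymus F_02 or KO thymus M_02, 4 without HT thymus M_01 and 5 without KO thymus F_02. Ly6d, a gene of early B and epithelial cells, fell by 0.60 on the log2 scale and was named after its value was seen.

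Lists of HT thymus were read in the same way. Between HT and WT, 7 lists were called with the preset correlation and 0 with the estimated one. Thymic epithelium markers such as Krt8 (+0.81) and Foxn1 (+0.34) averaged +0.42. Fibroblast markers such as Sparc (+0.63) averaged +0.23, and -0.019 without HT thymus F_01. T cell receptor genes such as Cd3g (+0.24) averaged +0.09, neutrophil markers such as Ltf (-0.99) averaged -0.61, mitosis genes such as Kif11 (-0.21) averaged -0.12, replication genes such as Tyms (-0.33) averaged -0.09 and NDR and Hippo pathway genes averaged -0.06. Between KO and HT, 6 lists were called with the preset correlation and 0 with the estimated one: neutrophil markers (-0.89), thymic epithelium (-0.53) and fibroblast markers (-0.28) were lower, and interferon (+0.31), mature T cell (+0.21) and mitosis genes (+0.09) higher. Several of these list values rested on single arrays. In HT against WT without HT thymus F_01, mitosis averaged -0.064 (adjusted p = 0.0561), replication -0.072 (adjusted p = 0.134), the NDR and Hippo pathway -0.044 (adjusted p = 0.0561) and thymic epithelium +0.25. Without HT thymus M_02, replication averaged -0.039 (adjusted p = 0.321), T cell receptor genes +0.073 (adjusted p = 0.132) and mitosis -0.067. Without WT thymus F_01, neutrophil markers averaged -0.35 (adjusted p = 0.0581), fibroblast markers +0.18 (adjusted p = 0.118), replication -0.076 (adjusted p = 0.0593) and T cell receptor genes +0.079 (adjusted p = 0.0683). T cell receptor genes also lost their call without HT thymus F_02 (+0.076), and replication without WT thymus M_02 (-0.079). Calls that stayed but moved were thymic epithelium without WT thymus F_02 (+0.27), replication without HT thymus M_01 (-0.15), mitosis without WT thymus M_02 (-0.071) and neutrophil markers without WT thymus M_01 (-0.99) or M_02 (-0.39). In KO against HT without HT thymus F_01, fibroblast markers averaged -0.026 (adjusted p = 0.661) and mitosis +0.036 (adjusted p = 0.354). Mitosis averaged +0.038 (adjusted p = 0.258) without HT thymus M_02, +0.13 without F_02 and +0.14 without M_01. Fibroblast markers averaged -0.20 (adjusted p = 0.324) without KO thymus F_01, and neutrophil markers lost their call without HT thymus M_01 (-0.75) or KO thymus F_01 (-0.81).

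Tumors of the 3 genotypes were compared to ask whether NDR1 loss marks the tumors that arise. Baiap3 again had the smallest p of the genes lower in tumors labelled KO, at -3.85 against WT, but it did not pass. The B cell genes Cd79b (+3.71) and Jchain (+3.35) had high values in some tumors labelled KO, and neither passed. No gene passed in limma in any of these comparisons. The number at unadjusted p under 0.05 was 473 for KO against WT, 390 for HT against WT and 154 for KO against HT. Against WT, the KO tumors had Baiap3 at -3.85 (SE 0.697, adjusted p = 0.522), Mpst at -2.16, Ccn6 at -0.71, Hspa1b at +2.59, Pqlc3 at +1.90 and Dhrs11 at +1.65. HT tumors had Rundc3b at +3.77, Pqlc3 at +1.98, Tada2b at +1.06, Mpst at -1.83, Cbfa2t3 at -1.69 and Slc6a9 at -1.52. KO against HT tumors had Baiap3 at -3.56 (adjusted p = 0.371), Zfp763 at -2.49, Il10 at -1.96, Cbfa2t3 at +1.46, Armc3 at +1.08 and Usp5 at +0.63. Leaving out KO tumor 07 gave 1 gene in KO against WT and 1 in KO against HT.

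The chromosome 17 genes of the KO thymus were read again in the tumors, a test chosen after the thymus result was seen. Of the 15 genes, 13 went the same way in KO against WT tumors, while Zfp52 and Zfp943 did not. Of the 10 genes on other chromosomes 8 did, while Nron and Plpbp, the latter named after its value was seen, did not (Fisher's exact p = 1 for a difference between these shares). A score, the mean of the 15 genes signed by their thymus change, was 0.557 ± 0.303 (SD, n = 7) in KO, -0.191 ± 0.598 (n = 7) in HT and -0.513 ± 0.440 (n = 5) in WT tumors. The exact permutation p was 0.00126 for KO against WT, 0.0146 for KO against HT and 0.342 for HT against WT. The same score of the 10 genes on other chromosomes was 0.885 higher in KO than WT tumors (exact permutation p = 0.0960).

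B cell and plasma cell markers differed widely between single tumors. The list mean was 8.54 ± 3.10 (SD, n = 7) in KO, 7.62 ± 3.13 (n = 7) in HT and 5.96 ± 1.24 (n = 5) in WT tumors, against 5.90 ± 0.316 over 12 thymi. The highest were KO tumor 06 at 12.66, KO tumor 04 at 12.42, HT tumor 01 at 12.41 and HT tumor 03 at 11.04, and the next tumor was at 10.05. In camera with the preset correlation 15 lists were called in KO against WT, 16 in HT against WT and 5 in KO against HT, and 0 of them with an estimated correlation (adjusted p = 0.356 to 0.950). In KO against WT, B cell markers averaged +3.01, interferon response +1.35, mature T cell genes +1.19, mitosis -1.17, replication -0.64 and double-positive thymocyte genes -1.03, with 0 members of any of these lists past the threshold. In HT against WT, B cell markers averaged +2.09, NK markers +1.53, fibroblast markers -1.32 and MYC targets -0.65. In KO against HT, double-positive genes averaged -0.88 and MYC targets +0.30. Without the 4 tumors of highest B cell list mean, an alternative chosen after seeing the data, KO against WT gave +1.23 for B cell markers, +0.37 for interferon response (adjusted p = 0.105), +0.26 for mature T cell genes (adjusted p = 0.633), -0.27 for mitosis, -0.066 for replication (adjusted p = 0.293) and -0.23 for double-positive genes (adjusted p = 0.141). HT against WT then gave +0.27 for B cell markers (adjusted p = 0.647), -0.10 for NK markers, -0.88 for fibroblast markers and -0.39 for MYC targets, and KO against HT gave -0.43 for double-positive genes and +0.37 for MYC targets. The 3'/5' ratio of the RNA was 0.336 ± 0.0678 (SD) over the 12 thymi and 1.33 ± 1.17 over the 19 tumors, of which 15 were above the highest thymus. Over tumors, 3210 genes followed this ratio in limma.

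**Figure D3:**
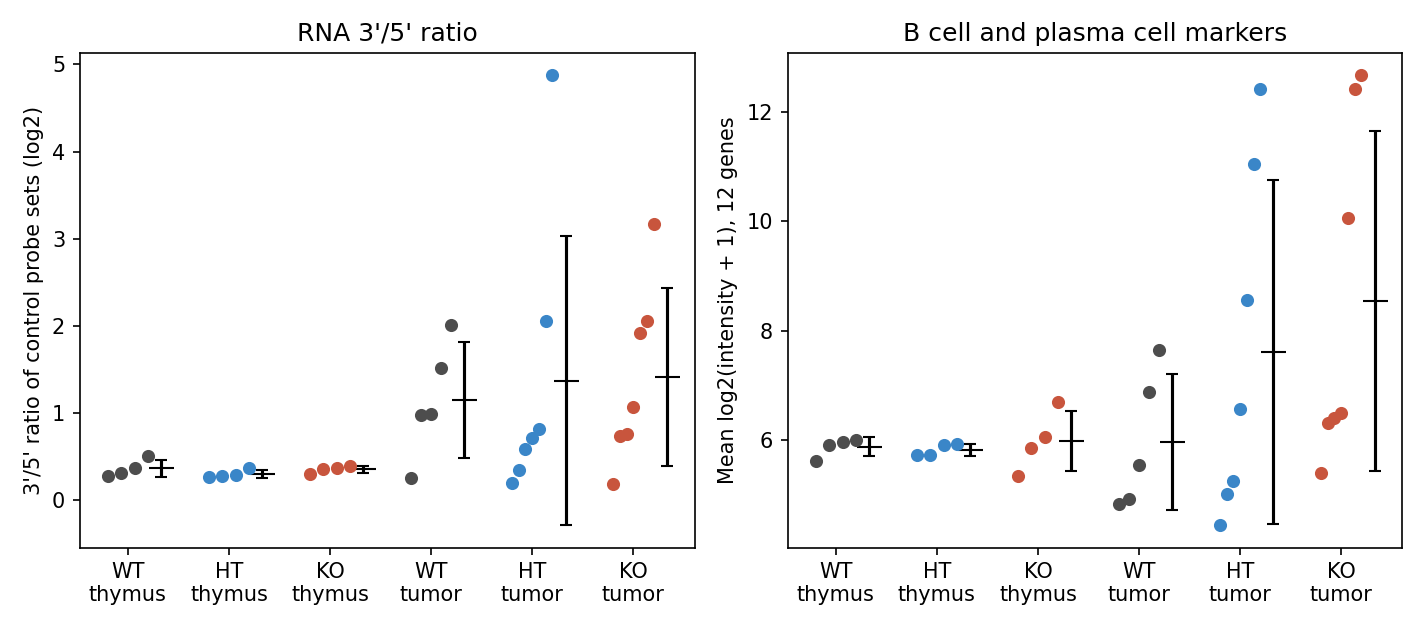
The 3'/5' ratio of control probe sets (log2) and the mean log2(intensity + 1) of 12 B cell and plasma cell markers on each array, by genotype and tissue, with group mean and SD beside the points. Thymi lie within 0.261 to 0.499 for the ratio, while HT tumor 07 reached 4.87; the B cell mean reached 12.66 in KO tumor 06.

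Tumors were compared with thymus to find how ENU-induced thymic tumors differ from it on average. The tumors had on average higher Notch1, Dtx1 and Nrarp, the receptor and targets of the Notch pathway that drives T cell leukemia. They had higher sugar-use genes such as Hk2 and Aldoa. Cd4, Cd8a and Cd8b1, expressed in double-positive thymocytes, the main cells of normal thymus, were lower, as was Prss16 of the thymic epithelium. The double-positive list lost its call with an estimated correlation (adjusted p = 0.0611). In limma 3390 of 14017 genes passed (24.2%), 1623 higher and 1767 lower in tumors. With the 3'/5' ratio as a covariate, chosen after seeing the data, 2522 passed, 1116 higher and 1406 lower. All tumors came from mice given ENU, up to 9 months after it, and all thymi from untreated mice. Tumor state therefore cannot be told apart from ENU exposure and the time since. The largest rises were Sall3 (+6.57, SE 0.847, adjusted p = 2.8e-06), Wdr25 (+5.82), Fbp1 (+5.65), Adamts20 (+5.48), Jdp2 (+5.04), Pdgfrb (+5.03), Asns (+4.94), Dtx1 (+4.87, adjusted p = 1.02e-09), Trim2 (+4.86) and Tox2 (+4.75). The largest falls were Dgkeos (-7.50, SE 0.177, adjusted p = 8.16e-22), BB031773 (-5.88), Prss16 (-5.68), Tctex1d1 (-5.67), Slc6a19 (-5.18), Tbata (-5.18), Tox3 (-4.76), Adam12 (-4.72), Insl5 (-4.71) and Sgk3 (-4.67). Stk38l fell by 0.96 on the log2 scale (adjusted p = 0.00801), and by 0.60 with the 3'/5' ratio as a covariate, where its adjusted p was 0.0562. Stk38 did not pass (-0.07), nor did Bcl2l11 (+0.13), whose probe sets went opposite ways.

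Lists gave the tissue difference by cell type and pathway, with 12 called by the preset correlation and 1, glycolysis, with an estimated one. Glycolysis genes averaged +0.89, and 8 of 14 rose, including Hk2 (+2.31), Slc2a3 (+2.24), Pfkl (+1.65) and Aldoa (+1.31) (adjusted p = 1.72e-05, and adjusted p = 0.0331 with an estimated correlation). Of 16 Notch pathway genes 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, with Dtx1, Nrarp (+2.33), Notch1 (+2.03) and Mfng (+1.15) among those that rose (adjusted p = 0.132 with an estimated correlation). The Notch list mean was 7.328 in HT tumor 01, 7.403 in KO tumor 04 and 7.297 in KO tumor 06, 3 of the 4 tumors of highest B cell list mean, within the range of the 12 thymi (7.122 to 7.601). Notch1 in these 3 was 11.37, 11.26 and 11.08, against 11.34 ± 0.293 (SD) over 12 thymi, whereas Dtx1 was at least 9.936 in every tumor and at most 8.235 in thymus. Of 20 MYC target genes 14 rose, such as Rrp1b (+1.38), Polr1b (+1.33), Odc1 (+1.05) and Mybbp1a (+0.96) (adjusted p = 0.332 with an estimated correlation). Of 13 double-positive thymocyte genes 10 fell, and 11 adjusted over the list alone, including Cd4 (-3.59), Cd8b1 (-3.36), Cd8a (-2.31) and Satb1 (-1.30) (adjusted p = 0.0611 with an estimated correlation). Of 14 T cell receptor signalling genes 11 fell, such as Cd5 (-3.26), Cd28 (-2.40), Cd247 (-1.72) and Lcp2 (-1.35), and 1 rose (adjusted p = 0.103 with an estimated correlation). Of 13 thymic epithelium markers 8 fell, with Prss16, Krt8 (-3.28), Psmb11 (-1.80) and Trp63 (-0.92) (adjusted p = 0.103 with an estimated correlation). Of 13 fibroblast and matrix markers 7 rose, such as Pdgfrb, Col1a2 (+4.17), Col3a1 (+3.17) and Col1a1 (+1.54) (adjusted p = 0.439 with an estimated correlation). Macrophage markers averaged +0.67 with C1qb (+1.49) and Cd68 (+0.88) rising. Mitosis genes averaged -0.55 with Ccnb2 (-1.33) and Nusap1 (-1.01) falling, and immediate early genes -0.85 with Egr1 (-3.64), Zfp36 (-2.30), Nr4a1 (-2.28) and Btg2 (-1.28) falling. Interferon response genes averaged -0.80, with Ifit1 (-2.91), Rtp4 (-1.69) and Ifit2 (-0.86) falling but Usp18 (+1.68) rising, and neutrophil markers averaged -1.20 with S100a9 (-3.18) falling. These last 5 lists had an adjusted p = 0.686 to 0.755 with an estimated correlation. The mitosis mean was 11.24 ± 0.193 (SD, n = 5) in WT tumors and 11.12 ± 0.0968 (n = 4) in WT thymus, and the list gave -0.23 (adjusted p = 0.205) without the 4 tumors of highest B cell list mean and -0.38 (adjusted p = 0.107) without HT tumor 04. Macrophage markers gave +0.48 (adjusted p = 0.110) without those 4 tumors, and +0.58 without WT tumor 03 (adjusted p = 0.0599) or KO tumor 02 (adjusted p = 0.0624). Interferon response lost its call without WT tumor 02 (-0.75), HT tumor 04 (-0.65) or KO tumor 02 (-0.76), neutrophil markers without HT tumor 04 (-0.999) or KO tumor 02 (-1.13), and immediate early genes without KO tumor 02 (-0.74). These 3 lists also lost their call with the 3'/5' ratio as a covariate, chosen after seeing the data (adjusted p = 0.102 for interferon response and 0.0520 for the others), with no sex covariate (adjusted p = 0.0953 and 0.0525) and with female arrays only (adjusted p = 0.125 for interferon response and neutrophil markers, 0.121 for immediate early genes).

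The other 16 lists were not called in tumors against thymus, although single members passed. Of 20 T cell leukaemia genes 4 rose, including Lyl1 (+3.33) and Lmo1 (+2.55), and 4 fell, including Rb1 (-0.76) and Ets1 (-0.68). Of 15 p53 targets 5 rose, including Phlda3 (+2.25), and 3 fell, including Fas (-1.83). Of 25 NDR, MST and Hippo pathway genes 1 rose and 5 fell, with Stk26 (-0.93) and Stk24 (-0.71) beside Stk38l. Of 11 double-negative genes Hes1 (+3.36) rose, while Rag2 (-3.39) and Rag1 (-2.30) were among 3 that fell. Of 16 mature T cell genes Runx3 (+1.70) rose, and Egr2 (-3.39) and Cd69 (-3.25) were among 5 that fell. Bcl2l1 (-2.35) fell in the anti-apoptotic list that was too small to test. These genes were picked after their values were seen. Camera adjusted p was 0.497 for BCL2 family pro-apoptotic genes (mean +0.06), 0.497 for DNA replication and S phase (-0.06), 0.250 for early thymic progenitor genes (+0.91), 0.0892 for DNA repair of alkylation and mismatches (+0.33), 0.865 for NF-kappaB targets (-0.08) and 0.278 for B cell and plasma cell markers (+0.94). It was 0.378 for dendritic cell markers (-0.05), 0.644 for NK and cytotoxic cell markers (-0.32), 0.212 for erythroid markers (-0.80), 0.602 for endothelial markers (+0.11) and 0.402 for adipocyte markers (+0.57).

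**Figure D4:**
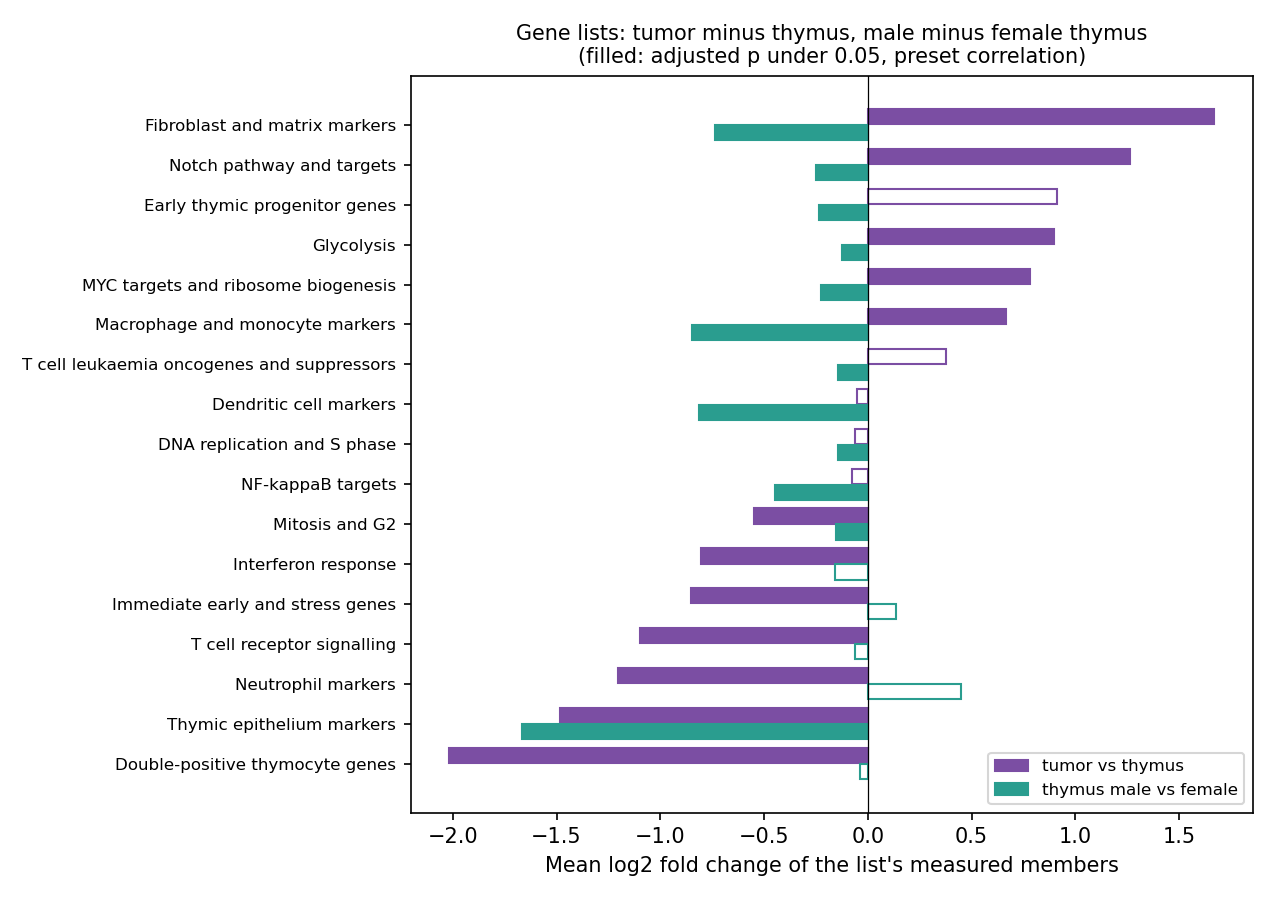
Mean log2 fold change of the measured members of each list called in either comparison, for tumors minus thymus (19 and 12 arrays) and male minus female thymus (6 each); filled bars had a camera adjusted p under 0.05 with the preset correlation. Double-positive thymocyte genes averaged -2.02 in tumors, and thymic epithelium markers averaged -1.67 in male thymi.

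Within genotypes, Sall3, Wdr25 and Fbp1 were among the 5 largest rises and Dgkeos and BB031773 among the 5 largest falls in each. No other gene was at the top in every genotype, though Prss16 was in WT and HT and Tctex1d1 in HT and KO. In WT 920 genes passed (403 higher, 517 lower), led by Sall3 (+8.12), Adamts20 (+7.74), Wdr25 (+7.10), Fbp1 (+6.64) and Col1a2 (+6.25), and by Dgkeos (-7.60), Slc15a2 (-6.92), Prss16 (-6.18), Sgk3 (-5.70) and BB031773 (-5.66). Slc15a2 did not pass in HT (+2.69, adjusted p = 0.515) or KO (+0.63, adjusted p = 0.867). In HT 491 passed (166 higher, 325 lower), with Sall3 (+6.21), Pdgfrb (+5.36), Wdr25 (+5.22), Fbp1 (+5.18) and Jdp2 (+5.13) highest and Dgkeos (-7.76), BB031773 (-6.22), Prss16 (-5.92), Tbata (-5.57) and Tctex1d1 (-5.56) lowest. In KO 667 passed (295 higher, 372 lower), with Sall3 (+5.37), Fbp1 (+5.14), Wdr25 (+5.14), Trim2 (+4.95) and Naip5 (+4.75) highest and Dgkeos (-7.12), Tctex1d1 (-5.98), Bex1 (-5.96), BB031773 (-5.77) and Slc6a19 (-5.26) lowest. Some of these genes depended on the settings. Pdgfrb in HT lost the threshold in 12 of 24 alternative settings, Fbp1 in 10 of 24 in HT and 10 of 24 in KO, and Slc15a2 in WT in 7 of 22. Leaving out 1 thymus array lowered the counts of genes passing to as few as 366 in WT (without F_02), 228 in HT (without F_01 or F_02) and 294 in KO (without F_02). Glycolysis was called with an estimated correlation in WT (adjusted p = 0.0162), HT (adjusted p = 0.0448) and KO (adjusted p = 0.0241), thymic epithelium in HT (adjusted p = 0.0483) and double-positive genes in KO (adjusted p = 0.0241). No gene passed the test of whether the change differed between HT and WT or between KO and WT in limma, with 147 and 119 genes at unadjusted p under 0.05. The smallest p for HT belonged to Slc15a2 (+9.60), Rundc3b (+3.78), Hcn2 (+0.58), Mpst (-2.09), Iqcc (-1.44) and Ndufs5 (-0.95), and for KO to Sco2 (+1.23), Polr3e (+0.82), Slc15a2 (+7.54), Mpst (-2.25), Ccn6 (-0.94) and Celf4 (-1.43). Of the lists, 15 and 14 were called with the preset correlation and 0 with the estimated one.

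Male and female thymi were compared because the labels split the thymus samples by sex. Xist, which silences the second X chromosome of females, and the Y-linked genes Eif2s3y, Kdm5d and Uty gave the sex in the labels for all 12 thymi. Prss16, Krt8 and the tolerance gene Aire, of the thymic epithelium, were lower in males, as were Csf1r of macrophages and Itgax of dendritic cells. By list, 12 were called with the preset correlation, and all 12 lost their call with an estimated one (adjusted p = 0.160 to 0.623). In limma 3626 of 14017 genes passed (25.9%), 2128 higher and 1498 lower in males, of which 200 changed by at least 1 on the log2 scale. Eif2s3y (+8.15), Kdm5d (+6.998), Uty (+3.82), Orly (+2.49), H3c7 (+2.29), Adam12 (+1.53), Stard6 (+1.49), Mei4 (+1.38), Slc7a11 (+1.19) and Srp54b (+1.18) rose most. Xist (-9.47), Prss16 (-5.00), Dsp (-4.02), Adamdec1 (-4.00), Crip3 (-3.72), Krt8 (-3.70), Tnc (-3.59), Cxcl12 (-3.47), Snhg11 (-3.37) and Tbata (-3.35) fell most. Stk38 (-0.31, adjusted p = 0.0141) and Bcl2l11 (-0.24) were lower and Stk38l (+0.54, adjusted p = 0.00706) higher in males. Thymic epithelium markers averaged -1.67 with 10 of 13 lower, macrophage markers -0.85 with 12 of 15 (13 adjusted over the list alone), dendritic cell markers -0.82 with 7 of 10 and fibroblast markers -0.74 with 7 of 13. Besides Prss16 and Krt8 these held Krt18 (-2.94), Aire (-2.37), Csf1r (-1.53), Itgax (-1.77), H2-Ab1 (-1.35) and Dcn (-2.19). NF-kappaB targets averaged -0.45 with Cd83 (-2.02) and Traf1 (-1.44), Notch pathway genes -0.25 with Jag1 (-1.03), early progenitor genes -0.23 with Cd44 (-0.74), MYC targets -0.23 with Cad (-0.68), mitosis genes -0.15 with Plk1 (-0.35), replication genes -0.14 with Tyms (-1.12), leukemia genes -0.14 with Myc (-0.57) and glycolysis genes -0.12 with Hk2 (-0.31). Hk2 lost the threshold in 13 of 21 alternative settings, Orly in 11 of 20, Bcl2l11 in 8 of 21 and Stard6 in 6 of 21. The 18S ribosomal RNA control probe sets, looked at after this result was seen, averaged 7.86 ± 0.639 (SD, n = 6) in male and 5.91 ± 0.564 (n = 6) in female thymi (exact permutation p = 0.00216).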

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

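The tests of chance placement and of a chromosome segment around Stk38, of the male-lower cell type lists, of the 18S probe sets, and of RNA integrity and B cells behind the Stk38 spread were chosen after the results were seen. Other tests of explanations and the splits of the samples were chosen before the data were examined.

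Of 162 sets of group values (27 measures in 6 groups), 9 held a sample far from the rest. Chance gives about 1 in 20, so 9 is about the number that chance alone would give. Bcl2l11 was 12.16 in KO thymus F_02 against 11.92 to 11.95 in the others, and 10.56 in WT tumor 03 against 12.85 to 13.24. The 3'/5' ratio of HT tumor 07 was 4.873 against 0.189 to 2.06. The mean of the DNA repair list was 9.587 in HT thymus M_02 against 9.73 to 9.75, and 10.51 in WT tumor 04 against 10.12 to 10.21. The mitosis list was 10.98 in WT thymus M_01 against 11.16 to 11.19, and the MYC target list 9.903 in HT thymus M_02 against 10.24 to 10.28. The NDR, MST and Hippo list was 8.279 in HT thymus F_01 against 8.34, and the T cell receptor list 10.63 in HT tumor 05 against 11.49 to 11.84.

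The change from thymus to tumor differed between genotypes for 29 list means in camera with the preset correlation, and for 0 with an estimated one. For HT minus WT the difference was 0.1114 for the NDR, MST and Hippo pathway, -0.7565 for mitosis, -0.4781 for DNA replication, -0.6313 for MYC targets, 0.748 for mature T cell genes, -0.3272 for glycolysis and -0.3582 for DNA repair. It was 0.8611 for interferon response, 0.7355 for NF-kappaB targets, 0.585 for immediate early genes, 1.894 for B cell markers, 0.7372 for dendritic cell markers, 1.67 for neutrophil markers, 1.317 for NK markers and -1.511 for fibroblast markers. For KO minus WT the difference was -1.124 for mitosis, -0.5523 for DNA replication, -0.3271 for MYC targets, -1.075 for double-negative genes, -0.9267 for double-positive genes, 0.8517 for mature T cell genes and -0.3352 for DNA repair. It was 0.8926 for interferon response, 0.9828 for NF-kappaB targets, 0.8968 for immediate early genes, 2.65 for B cell markers, 1.031 for dendritic cell markers, 2.641 for neutrophil markers and -0.9184 for fibroblast markers. Among the 6360 probe sets with no single gene name, which the comparisons left out, 1 passed in KO against WT thymus and 897 in tumor vs thymus (385 higher, 512 lower).

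Genes called in KO against WT thymus, such as Baiap3 and Eme2, gathered on chromosome 17, on 1 side of Stk38 and 24 to 217 protein-coding genes from it. Chance placement was argued against by Fisher's exact p = 4.78e-14. Probe sets that read a sequence variant stay open and cannot be told apart from a change in transcript level. Of 15 other probe sets of these genes a share of 0.533 went the same way, and 3 went the opposite way. For 6 genes, Baiap3 among them, only 1 probe set was above the filter. A chromosome segment or local effect that goes with the targeted allele stays open, and would gather genes on the chromosome of Stk38. An effect of NDR1 loss that acts regardless of gene position would not. Fisher's exact test takes genes as independent, which neighbouring genes may not be, so its p-value may overstate the evidence. With that limit, Fisher's exact p = 4.78e-14 argues against an effect regardless of gene position for the 15 chromosome 17 genes as a set. Persistence in tumors could not tell these apart, since 13 of 15 genes on chromosome 17 and 8 of 10 on other chromosomes went the same way in tumors labelled KO (Fisher's exact p = 1).

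Male thymi had lower Prss16, Krt8, Csf1r and Itgax than female thymi. Fewer epithelial, macrophage, dendritic and matrix cells may explain the genes lower in males, since all 4 lists were lower with the preset correlation, though none was called with an estimated one. The genes higher in males had a median of 0.353 over 2014 autosomal genes, above the bound of 0.3 set before the data were examined. That bound was wrong because it assumed a share of RNA from these cells, which no value gives. Fewer such cells would also raise thymocyte genes in males. The mean of the double-positive list was 13.17 to 13.30 in male and 13.22 to 13.35 in female thymi. That of the T cell receptor list was 12.38 to 12.51 in male and 12.43 to 12.56 in female thymi. These values, no part of the test set before the data were examined, do not decide whether fewer such cells caused the higher genes. The arrays were scaled alike, which may hide a common rise, so this cause stays open. RNA integrity cannot be told apart from other causes. With the 3'/5' ratio as a covariate 3508 genes were called, past the bound against it set before the data were examined, but that bound was wrong because the ratio had little to remove. It was 0.348 ± 0.0866 (SD, n = 6) in male and 0.324 ± 0.0475 (n = 6) in female thymi (exact permutation p = 0.563), and 0 genes followed it over thymi in limma (1006 at unadjusted p under 0.05). A difference in RNA preparation or labelling stays open, since 18S control probe sets differed (exact permutation p = 0.00216, the smallest possible). Sex itself stays open and untested.

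Stk38 ranged from 8.73 to 13.08 over tumors labelled KO. Wrong genotype labels stay open. The chromosome 17 score was above the highest WT tumor in 7 of 7 of them, which had been set before the data were examined as the bound against wrong labels. That bound was too loose, because KO tumor 03, with Stk38 at 12.84, exceeded the highest WT tumor narrowly (0.114 against 0.103) and HT tumor 02, at 0.917, also lay above the WT tumors. Baiap3, looked at after its values were seen, was 3.40 in KO tumor 03, 3.81 in KO tumor 04 and 4.805 in KO tumor 06. These lay below every WT and HT tumor, of which HT tumor 05 was the lowest at 6.37. KO tumor 07, at 6.84, lay within the range of HT tumors and beside 6.90 in the lowest WT tumor. As a single gene picked from the thymus result, Baiap3 does not decide the labels. RNA integrity was argued against as the whole cause, but only weakly. A range of 6.54 residual SDs was left after the slope of WT and HT tumors and 6.14 after the KO tumors' own slope. The bound for this was set after the results were seen, and the second value passed it narrowly. The slope also rests in part on HT tumor 07, with a ratio of 4.87. As a part of the cause RNA integrity stays open, with r = 0.602 between Stk38 and the 3'/5' ratio in KO tumors (exact permutation p = 0.141, r = 0.764 without the 2 farthest). B cells among the tumor cells may contribute, with Pearson r = 0.869 between Stk38 and the B cell list (exact permutation p = 0.0381, Spearman rho = 0.786, exact p = 0.0480, r = 0.804 without the 2 farthest). Over the family of 4 relations the adjusted p were 0.0762 and 0.0960, so this does not hold after correction. In HT tumors Stk38 also went with the 3'/5' ratio (r = 0.760, exact permutation p = 0.0177, adjusted 0.0708; rho = 0.893, exact p = 0.0123, adjusted 0.0492; r = 0.759 without the 2 farthest).

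Splits of the samples were read as arguing against chance at a share under 0.05 of splits with as many genes. By that share they did so for thymus KO vs WT (26 genes, 1 of 35 splits, 0 in any other). They also did for thymus HT vs WT (3 genes, 1 of 35, highest other 0) and thymus KO vs HT (8 genes, 1 of 35, highest other 0). With 35 splits, the real one among them, 1 of 35 is the smallest share possible, and any count above the other splits reaches it. The other splits mix genotypes, which widens the spread within their groups. Chance is therefore not excluded for these thymus comparisons. The share was also under 0.05 for tumor vs thymus (3390, 1 of 100, highest other 103) and within WT (920, 1 of 100, highest other 579). The same held within HT (491, 2 of 100, highest other 709), within KO (667, 2 of 100, highest other 1001) and for thymus male vs female (3626, 1 of 100, highest other 51). Within HT and within KO 1 other split called more genes than the real one, so the splits say less there than in the rest. In all of these the other splits mix the groups compared, which widens the spread within them, and 1 of 100 is the smallest share possible. Chance is therefore not excluded by the splits here either. The splits say nothing about chance where 0 genes were called, since every split then has at least as many: tumor KO vs WT (0; 100 of 100 splits, highest other 4), tumor HT vs WT (0; 100 of 100, highest other 426), tumor KO vs HT (0; 100 of 100, highest other 2207) and the differences of tumor vs thymus between HT and WT and between KO and WT (0 each; 100 of 100, highest other 1). The splits with 426 and 2207 point to a structure of the samples, whose cause was not tested. The sides of the first had 3'/5' ratios of 0.592 and 2.24 and B cell list means of 7.585 and 6.01, and those of the second had ratios of 0.959 and 1.82 and B cell list means of 9.255 and 6.90.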

How the results depend on the processing

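The 3'/5' ratio as a covariate and leaving out the 4 tumors of highest B cell list mean were chosen after seeing the data. Over the alternatives, for the named genes past the threshold in the report, 4811 of 5134 values kept their direction and side of the threshold, 320 lost the threshold and 3 reversed. For the lists called the numbers were 3429 of 3834, 393 and 12. Quantile normalization and centring on the 75th percentile had almost nothing to change, since the arrays had nearly the same quantiles. Quantile normalization moved log2 values by at most 0.000631. Both settings kept all 180 gene and 136 list values, so they test little. Leaving out each array gave 3111 of the 5134 gene values. A larger share was lost with female arrays only (48 of 119 gene values) and with only the 2 groups (22 of 60). Unless construction shows it (fewer arrays, a stricter threshold), the cause was not tested.

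With the mean of all probe sets per gene, thymus KO vs WT gave Zfp945 -0.12 and Gfer +0.082, tumor vs thymus gave Bcl2l11 -0.81 and thymus male vs female gave Phf6 +0.22, all reversed because probe sets of a gene differ in sign. That mean gave Stk38 a change of -0.25 in thymus KO vs WT (exact permutation p = 0.171) and -0.15 in thymus HT vs WT (exact p = 0.314). By limma the HT change of -0.42 had an adjusted p of 0.467.

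Genes past the threshold in thymus KO vs WT numbered 16 with no sex covariate, 8 with female arrays only, 12 with only the 2 groups compared and 13 with a log2 fold change of at least 1. Thymus HT vs WT gave 1 with no sex covariate, 1 with female arrays only and 1 with only the 2 groups. Thymus KO vs HT gave 5 with the mean of probe sets, 3 with no sex covariate, 1 with female arrays only, 2 with only the 2 groups, 15 with eBayes trend and robust, 5 with the fold threshold and 5 with the 3'/5' ratio. A replicate block gave 23, 3 and 8 genes in these thymus comparisons and 1 gene, Baiap3 (-4.56), in tumor KO vs WT, although the numbers do not pair the samples.

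Tumor vs thymus gave 1469 genes with female arrays only, 6485 with arrayWeights and 1544 with the fold threshold. Within WT the counts were 126 with female arrays only, 602 with only the 2 groups, 4271 with arrayWeights and 1641 without the 4 tumors. Within HT they were 141, 147, 2233 and 1369 in the same order, and within KO 90, 204, 2474 and 1611. Thymus male vs female gave 200 genes with the fold threshold.

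Without the 4 tumors, tumor HT vs WT gave -0.16 for mature T cell genes, -0.042 for interferon response, -0.047 for macrophage markers and -0.10 for NK markers, all reversed. The difference of tumor vs thymus between HT and WT gave -0.20 for mature T cell genes, -0.10 for interferon response, +0.046 for NF-kappaB targets and -0.17 for NK markers, and that between KO and WT +0.016 for mature T cell genes and +0.0057 for interferon response. For NF-kappaB targets and the last 2 lists it was camera's direction that reversed and not the mean. Over the arrays left out, fibroblast markers in thymus HT vs WT ranged from -0.019 (without HT thymus F_01) to +0.35, and mitosis in tumor KO vs HT from -0.63 to +0.14 (without KO tumor 06).

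The median SD within groups was 0.164 in HT thymus with no filter, 0.162 with the mean of probe sets and 0.132 with a pseudocount of 16. In KO thymus these were 0.173, 0.172 and 0.143, and in WT thymus 0.163, 0.158 and 0.132. In HT tumors it was 0.460 with no filter, 0.706 with a filter at the 50th percentile, 0.537 with the mean of probe sets and 0.536 with a pseudocount of 16. In KO tumors these were 0.495, 0.762, 0.584 and 0.579, and in WT tumors 0.341, 0.541, 0.403 and 0.397.

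Leaving out 1 array gave 13 to 23 genes in thymus KO vs WT, 1 to 3 in thymus HT vs WT, 2 to 6 in thymus KO vs HT, 0 to 1 in tumor KO vs WT and 0 to 1 in tumor KO vs HT (1 without KO tumor 07 in each). Within WT it gave 366 to 1088 genes, with 381 without WT thymus F_01, 366 without F_02, 557 without M_01, 600 without M_02 and 584 without WT tumor 04. Within HT it gave 228 to 571, with 228 without HT thymus F_01, 228 without F_02 and 294 without M_02. Within KO it gave 294 to 908, with 328 without KO thymus F_01, 294 without F_02, 428 without M_01 and 420 without M_02. Tumor vs thymus gave 2649 to 3678 and thymus male vs female 2852 to 3511. The Stk38 change ranged from -1.08 to -0.85 in thymus KO vs WT (exact permutation p = 0.0286 to 0.0571), from -0.48 to -0.36 in thymus HT vs WT (exact p = 0.0286 to 0.0571) and from -0.66 to -0.43 in thymus KO vs HT (exact p = 0.0286 to 0.0857). With 3 against 4 arrays the exact test has fewer arrangements. The median SD ranged from 0.153 to 0.172 in HT thymus, 0.162 to 0.188 in KO thymus, 0.154 to 0.172 in WT thymus, 0.515 to 0.627 in HT tumors, 0.548 to 0.668 in KO tumors and 0.412 to 0.446 in WT tumors. Genes near the lowest intensities have little signal over background, and their changes are compressed.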

Other observations

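The sex of the arrays was read from Xist and Y-linked genes. Xist was 13.22 to 13.52 in female thymi and 8.97 to 14.38 in female tumors, with WT tumor 03 the lowest. Male tumor KO 02 had Xist at 7.75 and Eif2s3y at 11.15. Male tumor HT 04 had Eif2s3y at 4.26 with Kdm5d at 9.31 and Uty at 8.66. Eif2s3y was at most 3.83 in female tumors.

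Rag1, Sall3 and Notch1, picked after their values were seen, were read in the 4 tumors with the most B cell marker signal. KO tumor 04 had Rag1 at 4.57, Sall3 at 4.16 and Notch1 at 11.26, and KO tumor 06 had Rag1 at 8.36, Sall3 at 4.82 and Notch1 at 11.08. HT tumor 01 had Rag1 at 12.42, Sall3 at 5.09 and Notch1 at 11.37, and HT tumor 03 had Rag1 at 12.01, Sall3 at 7.86 and Notch1 at 12.08. Over 12 thymi Rag1 averaged 14.73 ± 0.110 (SD), Notch1 11.34 ± 0.293 and Sall3 4.17 ± 0.301.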
